A study of Musca domestica with 29 samples.

How the data were processed

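RNA-seq was carried out on house flies (Musca domestica), with abdomen and head of individually dissected flies taken as separate samples, per the labels' protocols. Poly(A) RNA was extracted and made into libraries with the Illumina TruSeq Stranded mRNA kit. The 29 libraries comprised 12 male libraries from each tissue, from 4 genotypes with 3 replicates each, 2 libraries of female abdomen and 3 of female head. The replicates were labelled as biological, and nothing in the sources used here says that abdomen and head of the same number came from 1 fly.

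The submitters' processing notes name CASAVA 1.8, HISAT2 0.12.2, HTSeq 0.9.1 and DESeq2 1.16.1. The genome build is not given in the sources used here. Each tissue had 1 table of 16540 genes, of which 44 were transfer RNAs, and the tables were normalized separately, so no test was run across them. The values used here were the normalized counts per library deposited by the authors, a signal on a linear scale that divides read counts by 1 factor per library. Every value was a whole multiple of its library's smallest value (100% of values within a tolerance of 0.001 reads), so whole reads were recovered and their sums gave the depth, given in megareads (M reads). The tables also held the authors' own comparisons, deposited as a mean value, a log2 fold change and an adjusted p-value per gene. The mean values in these columns equalled the means of replicates 1 and 2 alone, within a relative difference of 4.97e-10, and their counts are given in the report as those of the authors' deposited table. The tables gave a Muller element per gene, where element A is the house fly chromosome III and element F the X chromosome. Of the gene identifiers, 13644 matched the reference gene table used for names and 2896 did not.

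Genes with a value of at least 10 in at least 3 libraries were tested, which left 11342 genes in abdomen and 12060 in head for comparisons among males, and 11486 and 12234 for the comparison of sexes. Values were analysed as log2(value + 1), and fold changes are on that scale, which understates the change of genes with low values. limma 3.58.1 was fitted in R 4.3.3 with a mean for each group and a variance trend with robust moderation, and genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The comparisons among males used the 12 male libraries of a tissue, and the comparison of sexes set the mean of the 4 male genotype means against the females. A count test had been written down for raw counts. Because the tables hold normalized values, limma was the main test, and edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. Python 3.11.15 and matplotlib 3.10.9 were used for the plots and permutation tests. Fold changes are given with standard errors from limma, and values as mean normalized read count ± SD over libraries.

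The groups, comparisons, tests, gene lists, rule for named genes and the first set of alternatives were fixed before the data were examined. For the pooled proto-Y types and for sex, the rule took, among called genes with a mean of at least 50 and no overlap between the libraries of the compared sides, the 10 largest changes in each direction, and for Y^M against Y^M(III) and between the III^M genotypes the 5 largest. It added the 3 called members of each list with the smallest p. The rule asked for a characterized product. As the tables hold no product names, it was applied to the 58 genes with a symbol in the tables or the reference. Of genes with a LOC identifier alone, those given, and the gene Sxl, were chosen after their values or the tables were seen. The sex-determination genes tra, tra-2, dsx, fru and CWC22 carry no such names in the tables and were not analysed here. The 19 planned lists each had fewer than 5 named members because product names are absent from the tables. The lists with any members were antimicrobial peptides with 4, heat shock proteins with 2 and cuticle proteins with 1, and they were described without a test. Groups of named genes (14 for xenobiotic metabolism, 4 antimicrobial, 5 chaperones, 9 nervous and sensory, 4 serpins and 3 superoxide dismutases) were put together after the tables were seen and tested with limma's camera at a preset correlation of 0.01 and with an estimated one. A planned test of whether the proto-Y difference itself differs between tissues was not run, since the tables were normalized separately.

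Shares of element A among called genes were tested with Fisher's exact test, two-sided, with a 95% interval of the odds ratio. The alternatives were TMM factors, no filter, a mean of at least 50, pseudocounts of 0.1 and 5, a replicate block, the other tools, the libraries of the compared groups only, and each library left out in turn. Alternatives chosen after the data were seen were replicates 1 and 2 only, a batch term for replicate 3, thinned reads, and leaving out both libraries under 1 M reads. Replicate numbers from the labels were checked for pairing by correlating the libraries' deviations from their group means across genes. In head all 18 correlations between libraries of the same number were above 0.1, with a minimum of 0.29, and in abdomen 17 of 18 were, the exception being Y^M and III^M #2 replicate 1 at 0.07. By that bound alone, the numbers were taken as pairing the male libraries, except for the abdomen comparisons that include that pair. Libraries of unlike numbers 1 and 2 also correlated, at a mean of 0.32 in head and 0.16 in abdomen. The means within number 1 and within number 2 were 0.4 and 0.35 in head and 0.2 and 0.29 in abdomen. The bound thus cannot tell pairing from replicate 3 standing apart. No pair of replicates agreed within sampling noise: chi-square per degree of freedom was 15.5 to 571.5 over 28 pairs, so each library counted as 1 sample.

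The fits were tested on simulated reads drawn from the real means and depths with 200 changed genes. For Y^M against III^M in abdomen, limma recovered 10.4% of the genes changed 2-fold and 54.6% of those changed 4-fold, and called 2 of 10939 unchanged genes. In head it recovered 27.6% and 79.8%, and called 3 of 11735. A change of 2-fold was mostly not recovered in this simulated comparison. The simulated libraries were drawn independently from a single mean per gene, without strain differences or a shift shared by replicate 3. These rates need not hold in the real data. A gene listed at 0 reads is limited by 3 reads of the library's total, which covers counting error only.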

Results

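The series measured gene expression in house flies whose males carried different young Y chromosomes (proto-Y chromosomes). In this species the male-determining locus can sit on several chromosomes, among them the Y (Y^M) and chromosome III (III^M). Males of 4 genotypes were assayed in abdomen and head with 3 replicates each: Y^M males of strain IsoCS, Y^M males of strain bwbCS (here Y^M(III), labelled as differing also in 1 copy of chromosome III), III^M males of strain CS (III^M #1) and III^M males of strain CSrab (III^M #2). Females came from IsoCS and CSrab for abdomen, and from IsoCS, CSrab and CS for head. The comparisons ask how proto-Y type, the copy of chromosome III, and sex relate to expression.

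Depth differed between libraries. In male abdomen, reads recovered ranged from 0.79 to 43.47 M, a 55.1-fold range, and both Y^M replicate 2 and III^M #2 replicate 2 held 0.79 M. Female abdomens had 30.53 and 13.9 M reads. In male head the range was 5.8 to 39.24 M, and the female heads lay between 28.99 and 29.84 M. For a gene at 0 reads, 3 reads allow up to 3.8 CPM in abdomen Y^M replicate 2, against 0.069 in replicate 3.

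Male libraries of replicate 3 lay apart from the others, in head along the first principal component. That component took 34.6% of the variance in abdomen and 38% in head. In head the replicate 3 libraries of all 4 genotypes lay at 34.2 to 84.8 on it and those of replicates 1 and 2 at −55.7 to −22.2. Deviations from genotype means correlated among the replicate 3 libraries at a mean of 0.52 in abdomen and 0.55 in head (across genes, which are not independent replicates). Between replicate 3 and the others the means were −0.32 and −0.44. These negative values largely follow from the positive ones, because the deviations within a genotype cancel out. Between replicate 3 and the other replicates, limma called 3550 genes in abdomen and 5911 in head.

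**Figure D1:**
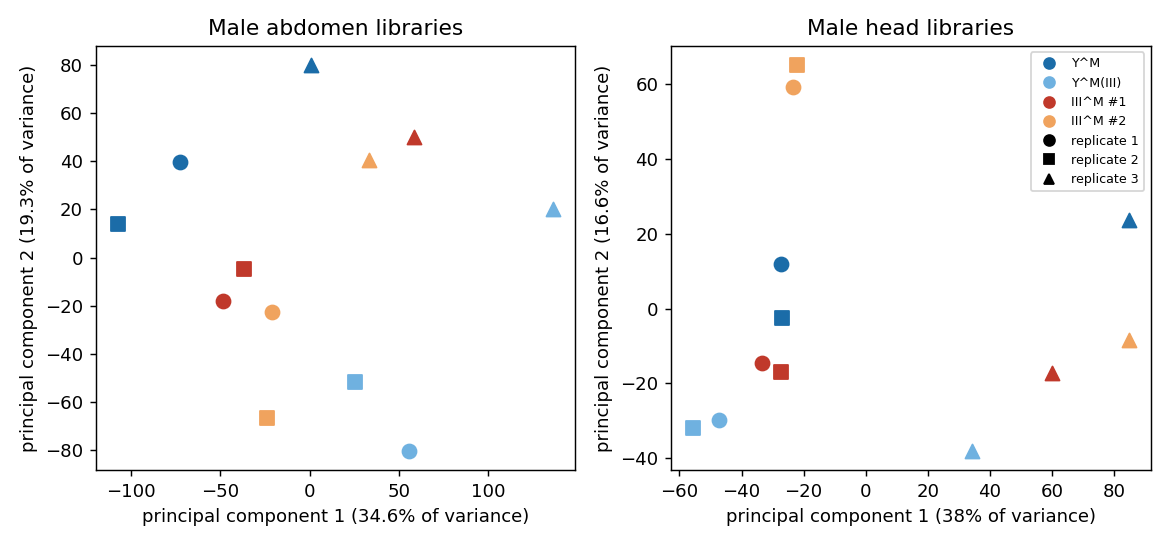
Principal components 1 and 2 of the male libraries, as log2(normalized read count + 1), with colour for genotype and marker for replicate number. In head, replicate 3 libraries lie at 34.2 to 84.8 on the first component (38% of the variance) and all other libraries at −55.7 to −22.2.

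Set against III^M heads, Y^M heads had less CPI transcript: 370 ± 72.5 (SD, n = 6) against 880 ± 284 (SD, n = 6), a log2 fold change of −1.20 (SE 0.15, limma adjusted p = 0.00536). Here n counts libraries, not strains, and limma's error holds only the spread of libraries within strains. For all comparisons of the pooled types, the adjusted p therefore does not measure variation between strains of a type. CPI was the only named gene called between the pooled proto-Y types in either tissue. By genotype it measured 395 ± 91.4 in Y^M, 346 ± 54.6 in Y^M(III), 641 ± 95.4 in III^M #1 and 1120 ± 147 in III^M #2 (n = 3 each). In abdomen CPI measured 1650 ± 542 in Y^M, 4080 ± 4400 in Y^M(III), 9430 ± 3240 in III^M #1 and 9200 ± 1580 in III^M #2, and the fold change of −2.12 (SE 0.44) did not pass the test (limma adjusted p = 0.2). Sxl, the homologue of the gene that sets sex in Drosophila, measured 1400 ± 86.1 in Y^M heads and 1520 ± 299 in III^M heads (log2 −0.10, limma adjusted p = 1). Of the gene groups, 0 of 13 tested xenobiotic genes and 0 of 5 chaperones, hsp20 and HSP70 among them, were called by limma between the pooled proto-Y types in either tissue, nor was any antimicrobial gene. Chitinase, the only cuticle list member, was too low to test, at 5.31 ± 3.59 in Y^M abdomens.

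Of unnamed genes, LOC101887630 was higher in heads of both Y^M genotypes, at 113 ± 30 and 132 ± 38.7, than in III^M #1 at 4.05 ± 3.33 and III^M #2 at 4.04 ± 3.95 (log2 4.94, SE 0.55, limma adjusted p = 0.00301). In female heads it measured 583 in the IsoCS strain, 37 in CSrab and 24.6 in CS. LOC101900684 was also higher, at 192 ± 106 against 15.5 ± 22.9 (log2 5.12, SE 0.89, limma adjusted p = 0.0367, n = 6 each). LOC105262326 was lower in both Y^M genotypes, at 54.7 ± 1.9 and 82.1 ± 34, against 401 ± 182 and 296 ± 55.7 in the III^M genotypes (log2 −2.33, SE 0.25, limma adjusted p = 0.00301). LOC101894694 was lower as well, at 17.1 ± 9.86 against 119 ± 91.8 (log2 −2.57, SE 0.42, limma adjusted p = 0.0218). In all, limma called 57 genes in head, 35 higher and 22 lower in Y^M. The Y^M and III^M libraries did not overlap in 19 of the 57, from which the unnamed genes above were taken. In the rest they overlapped. The replicate block gave 126 genes, replicates 1 and 2 alone gave 548, and the fit without Y^M(III) replicate 1 gave 26.

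In abdomen 3 genes were called between the proto-Y types, all without a symbol, with 727 at an unadjusted p under 0.05. The Y^M and III^M libraries did not overlap in 1 of the 3. LOC101891025 was higher in Y^M (log2 2.68, SE 0.26, limma adjusted p = 0.00776), and it also differed between III^M #1 and III^M #2 by 3.90. LOC105262206 was lower in Y^M (log2 −3.41, SE 0.42, limma adjusted p = 0.027), with a log2 of −5.07 between Y^M and Y^M(III). LOC109613915 was lower too (log2 −2.06, SE 0.25, limma adjusted p = 0.027), at 14.3 ± 6.73 in Y^M, 86.9 ± 16 in Y^M(III), 108 ± 10.4 in III^M #1 and 196 ± 35.8 in III^M #2 (n = 3 each). edgeR also called 3 genes, while leaving out 1 library at a time gave 1 to 10.

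Genes of chromosome III, which carries III^M, made up 7 of the 30 called head genes with an assigned element, 23.3% against 18.0% of such genes not called (odds ratio 1.39, 95% interval 0.5 to 3.35, Fisher's exact test p = 0.473, adjusted p = 0.797). With replicates 1 and 2 alone, chosen after the data were seen, they made up 102 of 414, or 24.6% against 17.7% of those not called (odds ratio 1.52, Fisher's exact test p = 0.000511). With the replicate block the odds ratio was 1.8 (Fisher's exact test p = 0.0253, adjusted p = 0.101). Replicates 1 and 2 alone gave an odds ratio of 2.30 between the III^M genotypes and 0.88 between Y^M and III^M #1. As a set, chromosome III genes had limma camera adjusted p = 0.734 with the preset correlation and adjusted p = 0.0147 with an estimated correlation, towards Y^M, with a median log2 of 0.03. Between the III^M genotypes these were adjusted p = 0.482 and adjusted p = 0.0496 with an estimated correlation, with a median of 0.10. Genes with no assigned element were 27 of the 57 called genes, 47.4% against 16.9% of genes not called (odds ratio 4.44, Fisher's exact test p = 1.02e-07).

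**Figure D2:**
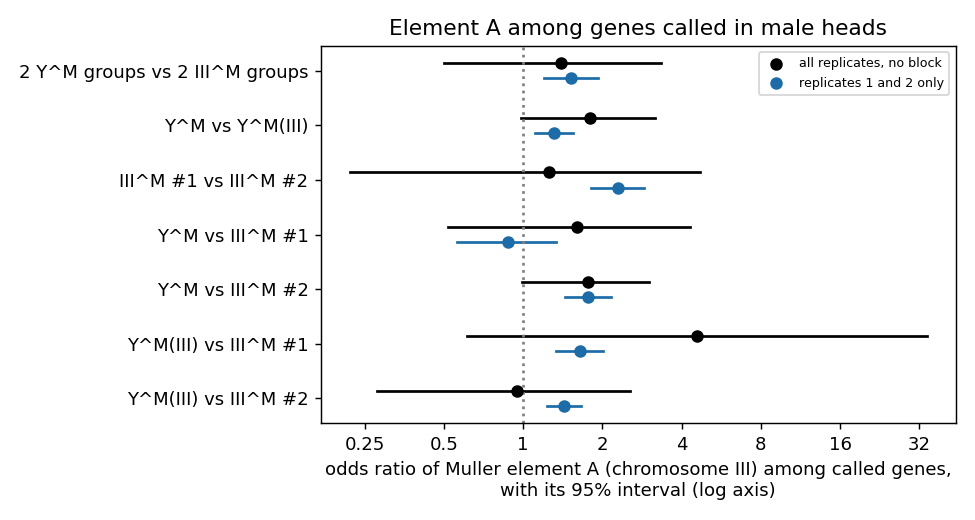
Odds ratio of Muller element A (chromosome III) among genes called in male heads, with 95% intervals on a log axis, for all replicates (black) and replicates 1 and 2 only (blue). For the pooled Y^M against the pooled III^M groups the ratio is 1.39 (0.5 to 3.35) with all replicates and 1.52 with replicates 1 and 2.

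Sex-biased genes were not over-represented among the head genes called between proto-Y types by this test. Of the 57 genes, 10 were also called between sexes, 17.5% against 16.3% of other genes (odds ratio 1.09, Fisher's exact test p = 0.722), 8 of them higher in males and 2 in females. Fold changes of comparisons with no library in common were compared across genes. Y^M against III^M #1 and Y^M(III) against III^M #2 correlated at −0.22 in abdomen and −0.24 in head. The remaining pairing gave −0.30 in abdomen and −0.07 in head. In abdomen 0 genes were called in the same direction in both comparisons of either pairing. In head the first pairing shared 2 genes, LOC101887630 and LOC109613917, both higher in Y^M (0.063 by chance). The remaining one shared LOC101887630, higher (0.072 by chance), and LOC105262326, lower (0.0046 by chance). In opposite directions, 1 gene was called in the first head pairing and 1 in the remaining abdomen pairing.

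Between Y^M and Y^M(III) abdomens, IR25a, a co-receptor for smell and other senses, was higher in Y^M at 314 ± 149 against 41.5 ± 32.5 (n = 3 each), 8.77-fold (log2 3.13, SE 0.77, limma adjusted p = 0.0313). Lysozyme, which breaks down bacterial cell walls, was lower in Y^M at 3.7 ± 3.56 against 182 ± 193 (log2 −5.04, SE 1.19, limma adjusted p = 0.0268). CYP12A2, a cytochrome P450, was lower at 120 ± 13.1 against 277 ± 67.8 (log2 −1.18, SE 0.23, limma adjusted p = 0.0137), and so was the superoxide dismutase SOD2 at 2090 ± 267 against 3560 ± 139 (log2 −0.78, SE 0.21, limma adjusted p = 0.0441). Each of these calls was lost on leaving out some single libraries. For example, limma's adjusted p was 0.121 for IR25a without Y^M replicate 1, 0.0999 for lysozyme without Y^M replicate 2 and 0.0558 for CYP12A2 without Y^M replicate 1, and SOD2 was lost whichever of the 6 libraries was left out (0.0769 to 0.147). The SOD2 call was also lost with edgeR (adjusted p = 0.069) and with no filter (limma adjusted p = 0.0536). The antimicrobial peptides diptericin (log2 8.19, SE 3.08), attacin (5.50, SE 2.16) and defensin-1 (3.78, SE 1.56) did not pass limma's test over all genes (adjusted p 0.13, 0.144 and 0.166); adjusted over the list alone, 3 members were higher and 1 lower. The higher values lay in Y^M replicates 1 and 2 only: replicate 3 measured 3.11, 3.26 and 69.3, within the ranges of Y^M(III) (0 to 13.8, 2.74 to 9.65 and 64.1 to 304).

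In all, 1047 abdomen genes differed between Y^M and Y^M(III), 857 higher and 190 lower in Y^M. LOC109612757 measured 386 ± 24.9 in Y^M and 1.51 ± 1.45 in Y^M(III) (limma adjusted p = 0.00146), and LOC109614376 measured 0.522 ± 0.78 and 1900 ± 814 (limma adjusted p = 0.00196). Leaving out single libraries gave 254 (without Y^M replicate 1) to 994 genes, edgeR gave 872, and the replicate block gave 2379. The balance of directions moved as well: 81.9% of the genes were higher in Y^M without the block, 61% with it (1451 higher and 928 lower) and 69.8% with DESeq2 (1382 and 597). Element A held 172 of the 872 called genes with an element, 19.7% against 17.8% of those not called (odds ratio 1.13, Fisher's exact test p = 0.166). In head 97 genes were called, 24 higher and 73 lower in Y^M, with no named gene among them. The block gave 172 higher and 259 lower, and replicates 1 and 2 alone gave 632 and 550, so the lean towards lower values in Y^M turned there. LOC109614160 measured 410 ± 200 in Y^M heads and 5.76 ± 2.61 in Y^M(III) heads (log2 5.89, SE 0.62, limma adjusted p = 0.00177). LOC101891053 measured 567 ± 283 and 16.7 ± 4.1 (log2 4.92, SE 0.82, limma adjusted p = 0.0207). LOC109613447 had 0 reads in all 3 Y^M heads, where 3 reads allow up to 0.517, 0.186 and 0.0814 CPM, and measured 251 ± 87.7 in Y^M(III) (limma adjusted p = 3.64e-06).

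The III^M genotypes differed from each other at few genes, and none of them had a symbol: 5 in abdomen and 21 in head. LOC105262551 was nearly absent from III^M #2, at 359 ± 294 against 0.962 ± 0.902 in abdomen (limma adjusted p = 0.0167) and 118 ± 17.5 against 0.47 ± 0.815 in head (limma adjusted p = 0.000236, n = 3 each). LOC105262582 in abdomen went the other way, at 1.63 ± 1.72 against 238 ± 46.4 (limma adjusted p = 0.00614), as did LOC105261537 in head at 3.64 ± 3.93 against 411 ± 72.4 (limma adjusted p = 0.000444). Sxl differed by −0.42 (log2) in head (limma adjusted p = 0.944). With replicates 1 and 2 alone, 477 head genes were called and Sxl passed at −0.56 (limma adjusted p = 0.0422).

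For the single pairs of proto-Y types, abdomen gave 8 genes for Y^M against III^M #1, 97 against III^M #2, and 21 and 45 for Y^M(III) against the same genotypes. Head gave 43, 102, 20 and 59. Leaving out single libraries moved these counts to 0 to 24, 7 to 50, 1 to 249 and 3 to 274 in abdomen, and to 9 to 50, 37 to 91, 2 to 47 and 18 to 75 in head. With the replicate block the abdomen counts were 41 for Y^M against III^M #1 and 479 and 599 for Y^M(III), and the head counts were 81, 241, 57 and 249.

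**Figure D3:**
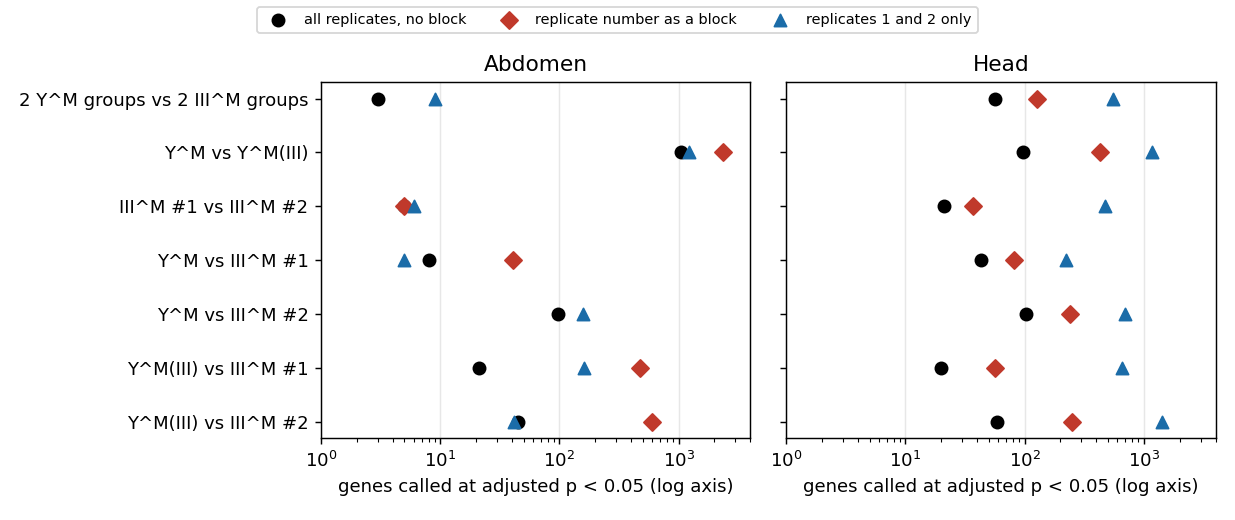
Genes called at a limma adjusted p under 0.05 in each comparison of males, on a log axis, for all replicates without a block (circles), the replicate block (diamonds) and replicates 1 and 2 only (triangles); diamonds are left out for abdomen comparisons whose numbers do not pair. Abdomen Y^M against Y^M(III), at 1047 genes without the block, lies above all other comparisons of males in that tissue.

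Detoxification genes were mostly higher in male than in female abdomens in a comparison that called 8195 of 11486 genes. The maternal egg gene bcd measured 181 and 78.2 in the female libraries and 0 to 3.4 in the male ones. Abdomens were sampled as a whole, so a different mix of organs in the sexes cannot be told apart from a difference in expression within organs. Of 13 tested xenobiotic genes, 12 were higher in males and 0 lower. GST-6A, a glutathione transferase, measured 18700 ± 6220 (SD, n = 12) in males and 884 ± 137 (n = 2) in females, 20-fold (log2 4.32, SE 0.3, limma adjusted p = 3.57e-07). The P450 CYP6D3, known from pyrethroid resistance, measured 17000 ± 6090 and 762 ± 351, 22-fold (log2 4.46, SE 0.39, limma adjusted p = 1.7e-06). The group's camera test gave an adjusted p of 0.000554 (limma), and an adjusted p of 0.114 with an estimated correlation. Other named genes higher in males were the small heat shock gene hsp20 (2800 ± 1160 against 100 ± 27.6, limma adjusted p = 1.74e-06), the water channel AQP (660 ± 290 against 18.1 ± 11.7, limma adjusted p = 2e-06), the serpin SPN9 (527 ± 260 against 12.6 ± 4.49, limma adjusted p = 1.61e-06) and CPI (6090 ± 4260 against 69.8 ± 73.2, limma adjusted p = 7.13e-06).

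Female abdomens had more yp3, a yolk protein gene, at 2970 ± 726 against 227 ± 252 in males (log2 −4.34, SE 0.76, limma adjusted p = 0.000296). The chaperonin subunit CCT-zeta was also higher in females, at 6030 ± 931 against 1730 ± 244 (log2 −1.80, SE 0.21, limma adjusted p = 1.42e-05). Sxl was higher in females at 749 ± 63.6 against 260 ± 47.6 (log2 −1.54, SE 0.2, limma adjusted p = 2.88e-05). Of 5 chaperones, hsp20 was higher in males and 3 were lower. The call of CCT-eta, 1 of these, was lost without female replicate 1 (log2 −0.34, limma adjusted p = 0.344) and against Y^M or Y^M(III) males alone (adjusted p 0.068 and 0.101). Of the serpins 2 were higher in males and 1 lower out of 4, and SPN13, 1 of the higher ones, was lost without female replicate 1 (log2 2.07, limma adjusted p = 0.115) and against Y^M males alone (adjusted p = 0.0513). Of the superoxide dismutases 2 of 3 were higher. The call of SOD2 was lost with TMM factors (log2 0.43, limma adjusted p = 0.0573), without female replicate 1 (0.31, adjusted p = 0.321) and against Y^M males alone (0.04, adjusted p = 0.885), where SOD was lost too (0.54, adjusted p = 0.186). Of the antimicrobial genes, defensin-1 was higher in males (log2 3.63, SE 1.43, limma adjusted p = 0.0387) and 3 of 4 were not called; adjusted over the list alone, 0 were. Defensin-1 measured 11700 and 7000 in Y^M replicates 1 and 2 and 64.1 to 630 in the other males. Its call was lost without either female (limma adjusted p 0.322 and 0.0559) and against Y^M(III), III^M #1 or III^M #2 males alone (0.26, 0.0629 and 0.262). Over all genes 4477 were called higher and 3718 lower in males. The median log2 fold change over all genes was 0.42, and 0.30 with TMM factors. Among unnamed genes, LOC101890350 measured 57600 ± 22700 in males and 0.387 ± 0.0843 in females, and LOC105261795 measured 33.1 ± 68.1 and 10800 ± 1000 (limma adjusted p = 8.21e-11 and 0.000138). With 2 female libraries from different strains, some calls rested on 1 of them: without female replicate 1, HR96 had a limma adjusted p of 0.1 and caspase-1 of 0.0679.

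In head the sexes differed less in count and several of the same genes lay on the other side. Females had more yp3 (2580 ± 3440, n = 3, against 63.9 ± 41.1, n = 12; log2 −4.59, SE 0.66, limma adjusted p = 0.000697) and more ODC, ornithine decarboxylase of polyamine synthesis (2320 ± 300 against 487 ± 171; log2 −2.32, SE 0.27, limma adjusted p = 0.000191). TPS measured 18900 ± 850 in females and 5270 ± 1440 in males (log2 −1.89, SE 0.24, limma adjusted p = 0.000286). CYP6D3 measured 15000 ± 697 in females and 9520 ± 1180 in males (log2 −0.67, SE 0.14, limma adjusted p = 0.00687), and MdaE7, a carboxylesterase linked to organophosphate resistance, 5960 ± 1030 and 3230 ± 380 (log2 −0.88, SE 0.14, limma adjusted p = 0.0015). GST, a glutathione transferase, was higher in males at 18900 ± 2410 against 7280 ± 904 (log2 1.37, SE 0.12, limma adjusted p = 3.49e-05). Sxl, higher in females in abdomen, was called higher in males in head at 1460 ± 218 against 1120 ± 129 (log2 0.37, SE 0.11, limma adjusted p = 0.0437). That call was lost without any 1 of the female libraries (limma adjusted p of 0.169, 0.0608 and 0.211) and with edgeR (adjusted p = 0.0518), and male and female libraries overlapped, from 1190 to 2020 and from 1020 to 1270.

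Of 14 xenobiotic genes tested in head, 1 was higher and 4 lower in males. LOC101891761, 1 of the lower ones, lost the call without female replicate 1 (log2 −0.55, limma adjusted p = 0.0748) and against Y^M(III) males alone (−0.37, adjusted p = 0.229). The camera test gave an adjusted p of 0.00263 (limma) downwards, and an adjusted p of 0.152 with an estimated correlation. Of 5 chaperones 2 were lower, CCT-zeta (log2 −1.15, SE 0.12, limma adjusted p = 9.79e-05) and CCT-eta (log2 −0.45, limma adjusted p = 0.00959). The call of CCT-eta was lost without female replicate 3 (limma adjusted p = 0.077) and against III^M #1 or III^M #2 males alone (adjusted p 0.189 and 0.092). Element F, the X chromosome, had a median log2 of 0.27, and its 6 called genes were all higher in males (camera adjusted p = 0.00263 in limma, and adjusted p = 0.101 with an estimated correlation). In abdomen its median was −1.49, towards females (camera adjusted p = 0.0651 in limma, and adjusted p = 0.114 with an estimated correlation); the difference between tissues was not tested. In all limma called 2015 genes, 784 higher and 1231 lower in males. LOC101890728 measured 7230 ± 3390 in males and 44.4 ± 22.9 in females, and LOC101889640 measured 2.68 ± 3.95 and 5440 ± 4900 (limma adjusted p = 3.13e-06 and 3.34e-06). The females did not pair with males by number. Setting them against males of replicates 1 and 2 alone gave 6432 genes, and against males of single genotypes 748 to 1482. Against males of replicate 3 alone, 2620 genes were called (1226 higher and 1394 lower in males). That fit took males of all genotypes as a single group with fewer libraries, so differences between strains entered its error. Its count is therefore not comparable with 6432.

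**Figure D4:**
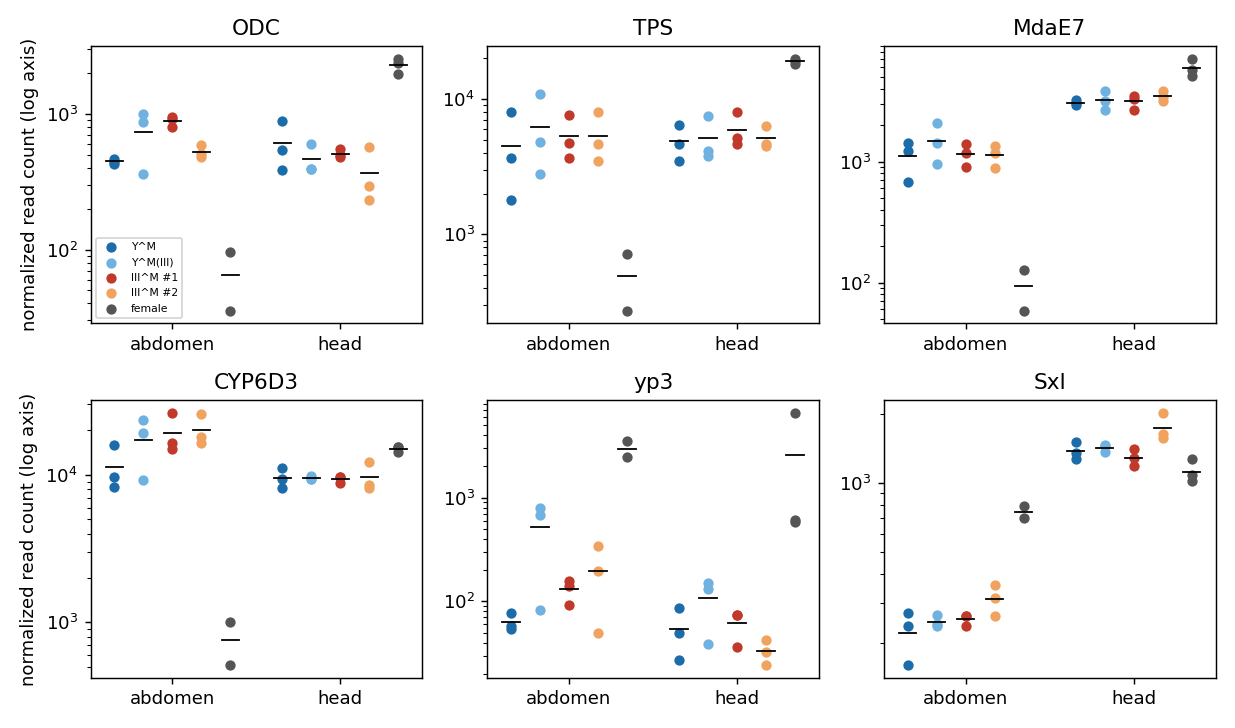
Normalized read counts on log axes of ODC, TPS, MdaE7, CYP6D3, yp3 and Sxl in each library, by tissue and group, with bars for group means. ODC averages 487 in male and 2320 in female heads, while CYP6D3 averages 17000 in male and 762 in female abdomens.

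Of 10345 genes tested for sex in both tissues, 227 were higher in males in both, where independent lists would give 240. Another 347 were lower in both, against 400 by chance, and 777 were called in opposite directions, against 643 by chance. Of the latter, 537 were higher in males in abdomen and in females in head. For Y^M against Y^M(III), 18 genes were lower in both tissues (0.95 by chance) and 6 higher in both (0.81 by chance). LOC101896776 had 0 reads in every Y^M, III^M and female library of both tissues and measured 556 ± 542 in Y^M(III) abdomens and 232 ± 202 in Y^M(III) heads (limma adjusted p = 0.00556 and 0.000442 against Y^M); it was chosen after its values were seen.

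Diptericin, an antimicrobial peptide induced by infection, varied widely between single libraries of a genotype. In Y^M it measured 8530, 41000 and 3.11 in abdomens of replicates 1 to 3 and 3090, 8540 and 5.39 in heads. In Y^M(III) the highest values were 13.8 in abdomen and 9.6 in head. Across the 12 genotype and replicate combinations, abdomen and head values correlated at Pearson's r = 0.99 and Spearman's rho = 0.99 (permutation p = 2e-05 each, the smallest that 100000 resamples can give, adjusted p = 6e-05 over 3 peptides). Without the 2 values farthest from the median r was 0.98 (n = 10), and within replicates 1 and 2 it was 0.99 (n = 8). Attacin gave r = 0.75 (permutation p = 0.0116, adjusted p = 0.0174) and rho = 0.43 (permutation p = 0.164), and its r without the 2 farthest values was 0.10, so that relation rested on them. Defensin-1 gave r = 0.52 (permutation p = 0.0619) and rho = 0.52 (permutation p = 0.0828).

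**Figure D5:**
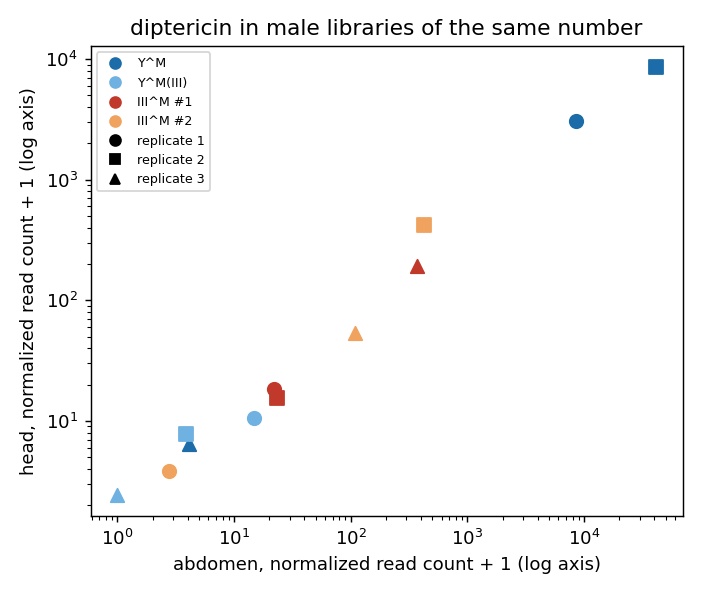
Diptericin in head against abdomen, as normalized read count + 1 on log axes, with 1 point for each genotype and replicate number of the males. Y^M replicates 1 and 2 lie highest, with 8530 and 41000 in abdomen and 3090 and 8540 in head.

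The authors' deposited table, which rests on replicates 1 and 2, lists 1159 abdomen genes for Y^M(III) against Y^M, 193 higher and 966 lower. The authors' deposited table lists 511 genes for III^M #1 against Y^M, 479 for III^M #2 against Y^M and 196 between the III^M genotypes. For head the authors' deposited table lists 878, 377, 525 and 739 genes in the same order. Element A among those head genes of the authors' deposited table had odds ratios of 1.40, 0.86, 1.51 and 1.78 (Fisher's exact test adjusted p = 0.00245, 0.431, 0.0025 and 6.66e-08).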

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

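The tests of females sharing the state of replicate 3, of the position of the females along it, of females at another point of that state, and of chromosome III acting on its own genes were chosen after the results were seen.

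Several genes were called in abdomen and had fold changes of the opposite sign in head. The difference between tissues was not tested, since the tissues were normalized separately. Between sexes, the mix of organs in the abdomen was not separated from expression within organs. IR25a was higher in Y^M than in Y^M(III) abdomens by 3.13 (log2) and measured −0.22 in head (limma adjusted p = 0.931). Between sexes, CYP6D3 was higher in male abdomens by 4.46 and lower in male heads (−0.67), MdaE7 by 3.75 (head −0.88), ODC by 3.38 (head −2.32), TPS by 3.42 (head −1.89) and LOC101891761 (CYP6A40) by 3.93 (head −0.62). HR96, a nuclear receptor, was lower in male abdomens at −1.84 and measured 0.38 in head (limma adjusted p = 0.116).

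Replicate 3 male libraries stood apart in both tissues. Depth as the cause was excluded in head: with every male library thinned to 5.8 M reads, the deviations of the 4 replicate 3 libraries still correlated at a mean of 0.47 (0.40 to 0.57 over 6 pairs), against 0.55 before. In abdomen the value after thinning to 0.79 M was 0.32 (0.21 to 0.39), and depth cannot be told apart there because that range spans the bound of 0.3 set for it. Whether female heads share the state cannot be told: the correlation of females over replicate 2 males with replicate 3 over replicate 1 males (0.48, abdomen 0.26) is above 0 without sharing, since replicates 1 and 2 are alike, and the females lay midway between both sets of males, at 0.54 (0.46 to 0.63). A batch of preparation or a shared condition of the flies may lie behind it, and no biological explanation was tested.

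Whether the sex difference in head is in part that state was not settled. Female 3 was a single library and the only CS female, so a comparison with it mixes the replicate state with strain. Genes called between males and females of numbers 1 and 2 had a median fold change of 0.27 (log2, signed by that comparison) in replicate 3 males against female 3, with 65.3% of 5501 genes in the same direction, against a median size of 0.78. That alone decided nothing, but 33.2% of the 2015 called genes (669) were called in the same direction against replicate 3 males and against the other males, with replicate 3 males farther from the females, which argues against the replicate state of the males as the whole cause. A batch of the females alone coincides with sex and cannot be told apart from it, so both stay open. Of 100 splits of the head libraries drawn, the real one included, 1 gave as many genes as the real 2015 (highest other 1208). A share of 1 in 100 is the smallest such a draw can give. It argues against chance for the count without excluding it, since the splits shuffled single libraries and so broke up strains and replicate numbers.

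More abdomen genes differed between Y^M and Y^M(III) than between any pair of proto-Y types. Thinning argued against depth, with 393 genes called against at most 27 for the proto-Y pairs. The 1047 called genes had a median absolute log2 of 3.34, with 857 higher and 190 lower, against a median of −0.044 over all genes. A factor shared by all genes of a library cannot give both, which argues against scaling as the cause of the count. For the lean towards Y^M scaling stays open. With TMM factors 81.9% of calls were higher in Y^M, but these factors moved the median of all genes only from −0.044 to −0.047. The share was 61% with the replicate block, 62.9% with the batch term and 69.8% with DESeq2. The odds ratio of element A was 1.13, against a direct effect of the chromosome III copy on its own genes as the cause. Effects of that copy on genes elsewhere, and other differences between the strains, stay open and are hypotheses.

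For the pooled proto-Y types, 4 of the 100 splits drawn gave as many genes as the real one in each tissue, the real one included. These splits shuffled single libraries and so broke up the strains. With so few strains per type, they cannot exclude that differences between strains, unrelated to proto-Y type, gave the counts. In abdomen the real count was 3 and the highest other 658, and in head 57 and 2036. Those larger counts came from splits that put the replicate 3 libraries together (4 against 0, or 3 against 1), which points to that structure of the samples. Among splits within replicate numbers, 1 of 100 was as large in each tissue, with highest others of 1 and 24. For each pair of genotypes the 10 splits are too few for a share under 0.05, and in every pair 1 split, the real one, was as large. The real counts in abdomen were 1047, 5, 8, 97, 21 and 45 for Y^M against Y^M(III), III^M #1 against III^M #2, Y^M against III^M #1 and III^M #2, and Y^M(III) against both, with highest others of 0 except 1 for the last. In head they were 97, 21, 43, 102, 20 and 59, with highest others of 0 except 40 for Y^M against III^M #2.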

How the results depend on the processing

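Replicates 1 and 2 only, the batch term for replicate 3, thinned reads, leaving out both libraries under 1 M reads, and males of replicates 1 and 2 or 3 against females were chosen after the data were seen.

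There were 1406 alternatives for 52 named-gene results, most of them sex differences and some of them Sxl results that did not pass. Of these alternatives, 1291 were counted as unchanged, 114 lost the call and 1 gained it (Sxl between III^M heads, with replicates 1 and 2 only). Of the results that were called, 0 reversed direction. For the Sxl results that did not pass, a change of direction was counted as unchanged. The 4 named genes called between Y^M and Y^M(III) abdomens, IR25a, lysozyme, CYP12A2 and SOD2, all lost the call with the compared groups only (limma adjusted p 0.0632 to 0.126) and without both shallow libraries (0.0548 to 0.139). The replicate block changed no call among these 52 results. Apart from those of Sxl, they were picked as called without the block, so new calls of other named genes would not show. Beyond the counts and odds ratios below, the block changed no other call that was refitted with it. For the sex results among the 52 the block is not valid, since females did not pair with males by number. Unless stated, the cause of a moved count was not tested. Thinned reads, left-out libraries and fits on the compared groups hold less data by construction. The lowest depth in abdomen was 0.79 M reads.

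Counts of called genes among males moved by over 1.5 times under many settings. In this paragraph pairs come in the order Y^M against Y^M(III), III^M #1 against III^M #2, Y^M against III^M #1, Y^M against III^M #2, Y^M(III) against III^M #1 and Y^M(III) against III^M #2, after the pooled types. DESeq2 gave 135 pooled and 1979, 26, 291, 617, 373 and 350 in abdomen, and 180 pooled and 343, 74, 142, 285, 88 and 223 in head. The replicate block gave 33 pooled in abdomen, then 2379, 41 for Y^M against III^M #1, 635, 479 and 599, and in head 126 pooled and 431, 37, 81, 241, 57 and 249. For abdomen, the numbers did not pair the pooled types or Y^M and III^M #2, although 11 of 12 libraries correlated best with their own number. The batch term gave 29 pooled in abdomen, then 2325, 58 for Y^M against III^M #1, 556, 499 and 614, and in head 169 pooled and 504, 58, 101, 324, 58 and 319. Replicates 1 and 2 only gave 9 pooled, 5, 159 and 161 in abdomen (pooled, Y^M against III^M #1 and III^M #2, Y^M(III) against III^M #1), and in head 548 pooled and 1182, 477, 224, 702, 652 and 1413.

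Other settings mostly lowered the counts, in the same order. A mean of at least 50 gave 652, 3, 4, 64, 1 and 24 in abdomen, and in head 37 pooled, 62, 26, 58, 4 and 39 (for the III^M genotypes, 14 against 21). The compared groups only gave 301, 1, 0, 63, 1 and 8 in abdomen, and 56, 8, 1, 41 and 2 in head for all but the last pair. Thinned reads gave 393, 2, 11 (Y^M against III^M #2), 7 and 27 in abdomen, and 33 pooled and 58, 12, 20, 57, 8 and 39 in head. Without both shallow libraries, abdomen gave 0 pooled and 247, 2, 0, 6, 1 and 7. Beside the counts of 0 in limma, 524 genes had an unadjusted p under 0.05 for the pooled types, for which edgeR on all libraries called 3 and DESeq2 135, and 878 (shallow libraries out) and 1002 (compared groups only) for Y^M against III^M #1, for which edgeR on all libraries called 6 and DESeq2 291. edgeR gave 2, 51, 3 and 28 in abdomen (III^M genotypes, Y^M against III^M #2, and Y^M(III) against both), and 12 and 9 in head (III^M genotypes, Y^M(III) against III^M #1). A pseudocount of 0.1 gave 1 pooled, 2, 2, 3 and 19 in abdomen (the III^M genotypes, Y^M against III^M #1, Y^M(III) against both) and 4 in head for Y^M(III) against III^M #1. A pseudocount of 5 gave 14 pooled and 160 for Y^M against III^M #2 in abdomen. With no filter the counts were 14 pooled and 16 for Y^M against III^M #1 in abdomen, and 33 for Y^M(III) against III^M #1 in head. TMM factors gave 38 for abdomen Y^M(III) against III^M #1.

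Leaving out 1 library at a time gave these lowest and highest counts; where a group kept 2 libraries its spread was pooled with the others. In abdomen the pooled types gave 1 (without III^M #1 replicate 1) to 10, Y^M against Y^M(III) 254 (without Y^M replicate 1) to 994, the III^M genotypes 1 to 12, Y^M against III^M #1 0 (803 at an unadjusted p under 0.05) to 24, Y^M against III^M #2 7 to 50, Y^M(III) against III^M #1 1 to 249 and against III^M #2 3 to 274, both highest without Y^M(III) replicate 2. In head they were 26 to 73 pooled, 22 to 86 for Y^M against Y^M(III), 7 to 61 for the III^M genotypes, 9 to 50 and 37 to 91 for Y^M against III^M #1 and #2, and 2 to 47 and 18 to 75 for Y^M(III). Sex gave 6330 to 8350 in abdomen and 867 (without female replicate 2) to 2582 in head.

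Sex in head moved to 3124 genes with the replicate block, 6432 against males of replicates 1 and 2, and 1000, 1037 and 748 against Y^M, Y^M(III) and III^M #1 males alone. The block is not valid for sex, since the numbers of the females stand for strains and did not pair with those of the males. The odds ratio of chromosome III among head calls had an unadjusted p under 0.05 at 1.8 with the block (Fisher's exact test p = 0.0253, adjusted p = 0.101, which does not pass), 1.52 with replicates 1 and 2 (Fisher's exact test p = 0.000511, adjusted p = 0.00143), 1.85 with the batch term (Fisher's exact test p = 0.00535, adjusted p = 0.02) and 2.04 with genes called at an adjusted p under 0.1 (not adjusted), and ranged from 0.96 (reversed, without Y^M replicate 2) to 1.74 on leaving out libraries. The odds ratio of sex-biased genes reversed to 0.96 with the block (Fisher's exact test p = 0.918) and ranged from 0.4 to 1.15 on leaving out libraries, on both sides of 1. Its value with the block also rests on the block for sex. The abdomen shares gave no value, as 0 of the 3 called genes had an assigned element and 3 genes were too few for the other share. Correlations of comparisons without shared libraries moved to −0.28 and −0.33 in abdomen and −0.31 and −0.05 in head with a mean of at least 50.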

Other observations

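The test of strain background in females and that of tissues coming from the same fly were chosen after the results were seen.

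Replicate 3 heads differed from those of replicates 1 and 2 at several named genes. MdRdl, a GABA receptor subunit, was lower by a log2 of −2.89 (limma adjusted p = 1.33e-05), HSP70 of −1.94 (limma adjusted p = 0.000104) and pdf, the clock neuropeptide, of −1.16 (limma adjusted p = 5.96e-05). Gr2 was higher by 3.14 (limma adjusted p = 0.0039), as were the P450 genes CYP6D8 by 1.92 (limma adjusted p = 0.000391) and CYP6G4 by 1.36 (limma adjusted p = 0.00127). In abdomen CYP6D8 (2.38, limma adjusted p = 0.0299) and CYP6G4 (1.90, limma adjusted p = 0.0138) were also higher in replicate 3.

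Genes that separated male strains often separated the females of those strains. LOC109614160, high in Y^M (IsoCS) male heads, measured 1240 in the IsoCS female head and 15.1 and 3.42 in those of CSrab and CS. LOC105262551, nearly absent from III^M #2 (CSrab), measured 0.755 in the CSrab female head, 293 in that of IsoCS and 179 in that of CS. LOC109613447, at 0 in Y^M heads, was at 0 in the IsoCS female head and measured 642 and 375 in those of CSrab and CS. LOC101887630, the gene higher in both Y^M genotypes, measured 583 in the IsoCS female head, 37 in CSrab and 24.6 in CS.

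Over all head genes called between males of IsoCS, CS and CSrab, 92.1% of the differences had the same direction between females of the same strains (151 of 164 with a difference, over 3 pairs of strains). Assigning the 3 females to strains in the 5 other ways gave 17.3 to 79.6%. Genes not called went the same way in 60.1 to 64.6%. In abdomen the share for IsoCS against CSrab was 84.6% (77 of 91), against 58.9% of genes not called. A candidate explanation is therefore a difference of strain background that both sexes carry, rather than the proto-Y chromosome itself; it rests on 1 female per strain, and whether females carried a proto-Y chromosome is not given in the labels.

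Diptericin followed the replicate number across tissues, which could arise if tissues of the same number come from the same fly. The differences of replicate 1 minus replicate 2 were correlated across genes between abdomen and head, leaving out the antimicrobial genes. The correlation with the head of the same genotype exceeded that with the other heads by 0.04 on average (0.02 to 0.06 by genotype), which is too small to decide. A shared exposure of flies of 1 number stays open.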
